A study of Homo sapiens with 2 samples.

How the data were processed

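RNA was sequenced from 2 libraries of primitive macrophages made from the human induced pluripotent stem cell line 1231A3, 1 labelled Control and 1 labelled PNU282987 (100 µM, 12 hours), both after 30 days of differentiation. Per the labels' protocols, libraries were made with a stranded mRNA kit. The treatment field of the PNU282987 library names amyloid β, against its title, library name and protocol; the library was grouped by its title. The deposited table gives whole read counts per locus, per the file headers, with no normalization. Per the submitters' processing notes, FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, StringTie 2.1.3b and edgeR were used with GRCh38; their order and settings are not given in the sources used here. Whether mates were counted singly, how multi-mapping reads were treated and whether strand was used in counting are not given either. Counts of 2 reads were more frequent than counts of 1 read in both columns (958 against 818 loci in Control, 979 against 817 in PNU282987), so a fragment may have been counted as 2 reads, and the counting intervals would then be too narrow. Overlapping and antisense loci are therefore treated as uncertain.

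The table held 46865 loci, 46287 annotated by NCBI gene identifier and 578 assembled loci; 44560 annotated loci had a position in the RefSeq annotation of GRCh38. Positions come from that annotation and count from 1. The total was 39316475 reads in Control and 36134391 in PNU282987, so the floor of 3 reads stood at 0.0770 and 0.0823 CPM. Totals were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, giving 0.991 for Control and 1.01 for PNU282987. CPM were computed from the counts and the scaled totals. With 1 library per group no test across samples can be made and no p-value is given. A locus was called higher or lower by a rule of size set before the data were examined: a ratio of at least 2-fold, an exact 95% Clopper-Pearson counting interval of the ratio that excludes 1, and a mean of at least 1 CPM. Intervals and floors cover counting error only. Loci on chromosome Y and XIST stayed in the library totals and were compared nowhere.

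The 42 gene lists were also set before the data were examined. The median log2 ratio of each list with at least 4 measured members was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. Loci with 0 reads in a library entered at their ratio against the floor of 3 reads. Genes named in the text are, by a rule set beforehand, the 10 highest and 10 lowest by the near end of the interval with a mean of at least 5 CPM, without assembled loci and pseudogenes; up to 4 members past the rule in each list, or the 2 most expressed where fewer than 2 passed; CHRNA7, CHRFAM7A, measured CHRNA subunits, ACTB and GAPDH; and the 5 genes with the most reads in each library. The text prints most but not all of the 110 genes this names, and some single-gene results are not reported here.

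The rule was tested on simulated counts for this comparison. With counting error alone, over 14259 loci, 98% of 50 loci changed 3-fold, 96% of 50 changed 4-fold and 100% of 50 changed 8-fold were called in the right direction, and 1 of 14062 unchanged loci was called. With an assumed spread of 20% between cultures, over 14233 loci, 292 of 14038 unchanged loci were called, or 2.08%. Of 40 simulated unchanged lists 1 fell outside the middle 95%, with and without that spread. Each locus varied independently in these simulations, so they do not cover lists whose members vary together. Alternatives covered other scalings (library totals, upper quartile, DESeq2 1.42.0 size factors), expression filters, thresholds, thinning of the deeper library, subsets of loci, halved counts, overlapping loci and a trend with GC content and transcript length. The last 3 were chosen after seeing the data. GC content and length were known for 92.3% of the loci compared. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.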

Results

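The series asked how gene expression in a human microglia model differs after exposure to PNU282987, a full agonist of the α7 nicotinic acetylcholine receptor. Cells of the human induced pluripotent stem cell line 1231A3 were differentiated for 30 days into primitive macrophages, the embryonic type of macrophage from which microglia descend. The PNU282987 library came from cells labelled as given 100 µM of the agonist for 12 hours, and the Control library from macrophages with no agonist in their labels; a vehicle is not stated. The labels of the PNU282987 library conflict: its title, library name and protocol name PNU282987, and its treatment field names amyloid β instead. There was 1 library per group, so no difference below has a replicate check, and every interval is a 95% counting interval that leaves out the spread between cultures. The Control library held 39316475 reads and the PNU282987 library 36134391 reads over 46865 loci, of which 578 were assembled loci without a gene identifier. FTL, the ferritin light chain, took the most reads in both libraries, 1.96% in Control and 1.71% in PNU282987, followed by SPP1, COX1 and CTSB in both. Mitochondrially encoded mRNA took 5.48% of the reads in each library.

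The receptor that the agonist targets was scarcely expressed in either library. CHRNA7 (chromosome 15, 32030483 to 32173018, GRCh38) had 83 reads in Control and 57 in PNU282987, or 2.13 CPM (exact Poisson interval 1.70 to 2.64) and 1.56 CPM (1.18 to 2.03). The log2 ratio of PNU282987 to Control was -0.45, with a counting interval of -0.96 to 0.06 that includes equality. With the trend over GC content and length removed, it was -0.66 (-1.17 to -0.15), which excludes equality, so whether CHRNA7 differed depends on that correction. CHRFAM7A (chromosome 15, 30360566 to 30393900), a partial duplicate of CHRNA7 that can share its reads, had 68 and 69 reads, and the split of reads between these loci is uncertain. Of the 19 nicotinic receptor subunits and chaperones, 4 reached a mean of 1 CPM and none of these 4 differed by 2-fold. Below that mean, RIC3 had 15 and 0 reads, CHRNA1 0 and 15 and TMEM35A 7 and 20, each with a counting interval that excluded equality; these 3 were singled out after their values were seen. CHRNB1, a muscle-type subunit, had 5.62 CPM in Control and 4.14 CPM in PNU282987, a log2 ratio of -0.44 (-0.75 to -0.13), or -0.29 (-0.60 to 0.012) with that trend removed, and CHRNA10 had 1.31 and 1.48 CPM. Among the other known or possible receptors of the ligand, the muscarinic receptor CHRM3 was 2.43-fold lower in the PNU282987 library, at 3.80 and 1.56 CPM.

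CYP24A1, G0S2, NR1I2 and FBP1 were among the genes with the greatest excess in the PNU282987 library. CYP24A1 (chromosome 20, 54143538 to 54173986), which encodes the enzyme that inactivates vitamin D hormone, had 0 reads in Control and 6763 in PNU282987. Against a floor of 3 reads in the Control library it was 2410-fold higher, and its counting interval reached down to 1959-fold. G0S2 (chromosome 1, 209675412 to 209676390), an inhibitor of triglyceride lipase, was 122-fold higher, from 1.54 to 188 CPM, with a log2 ratio of 6.93 (6.56 to 7.32). FBP1 (chromosome 9, 94603133 to 94640263), a gluconeogenic phosphatase, was 92.5-fold higher, from 2.26 to 209 CPM. NR1I2, the pregnane X nuclear receptor, had 4 and 499 reads, a log2 ratio of 7.06 (5.69 to 8.94). HBEGF, a ligand of the epidermal growth factor receptor, was 14.8-fold higher, and the acute-phase gene ORM1 13.5-fold higher, from 19.1 to 258 CPM. ORM2, a near-identical copy of ORM1, had a log2 ratio of 3.74 that became 0.011 with the reads of its overlapping locus added, and the division of reads between both copies is uncertain. ASAP2, which acts on Arf GTPases, had 4.23 and 76.0 CPM by its own reads, and its log2 ratio of 4.17 became 1.48 with the reads of overlapping loci added. Those loci also held more reads in PNU282987 than in Control. Here and below, such a sum moves toward the ratio of the overlapping loci whether or not reads were assigned between them. A smaller ratio after the sum alone does not show such assignment. The microRNA locus MIR1287 had a log2 ratio of 3.70 and 3.43 with the reads of its overlapping locus added. The libraries were made with an mRNA kit, so reads at microRNA loci, here and below, do not measure the mature microRNA. The readthrough locus ZNF765-ZNF761 had 2 and 637 reads, but its log2 ratio of 8.41 became 0.18 once the reads of the 5 loci it overlaps were added.

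On the lower side, PDK4 (chromosome 7, 95583499 to 95596516), a kinase that restrains pyruvate oxidation, was 7.36-fold lower in the PNU282987 library, at 242 CPM in Control and 32.9 CPM in PNU282987. CX3CR1 (chromosome 3, 39263494 to 39292966), the fractalkine receptor of microglia and monocytes, was lower at 29.8 and 4.96 CPM, a log2 ratio of -2.58 (-2.82 to -2.36). CIITA (chromosome 16, 10866206 to 10943021), the master regulator of MHC class II transcription, was 5.79-fold lower, at 33.7 and 5.82 CPM. Its log2 ratio of -2.53 became -1.11 with the reads of an overlapping locus added. That locus held no more reads in PNU282987 than in Control, so the sum does not show that reads of CIITA were assigned to it. RASAL1, a GTPase-activating protein of Ras, was 6.11-fold lower. MAGIX, a PDZ domain gene, had 530 and 17 reads, and ATP5ME, a subunit of ATP synthase, 821 and 102 reads. PCDHGA8, MIR7847, MIR6502 and MIR34AHG also ranked among the lowest, but each overlaps other loci. With the reads of those loci added, the log2 ratio of MIR7847 went from -12.33 to -0.73, that of PCDHGA8 from -4.29 to -0.16, that of MIR6502 from -4.15 to 0.12 and that of MIR34AHG from -7.01 to -3.77.

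**Figure D1:**
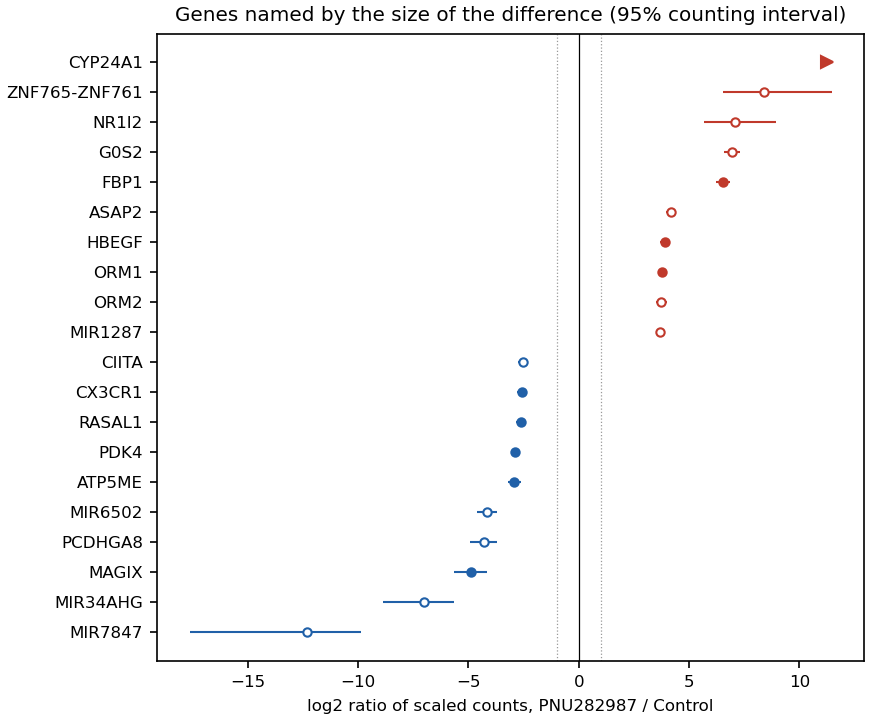
Log2 ratio of scaled counts, PNU282987 over Control, for the 20 genes named by the size of their difference, with 95% counting intervals as bars. Open circles are genes that overlap another annotated locus and filled circles those that do not. The triangle marks the ratio of CYP24A1, which had 0 Control reads, against the floor of 3 reads, and dotted lines mark 2-fold. FBP1 lies at 6.53 and PDK4 at -2.88.

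Across the 14265 loci with a mean of at least 1 CPM, 423 were at least 2-fold higher and 401 at least 2-fold lower in the PNU282987 library with a counting interval that excluded equality. Together they made up 5.78% of the loci compared. Of the 14230 compared loci with reads in both libraries, 82.6% lay within 1.5-fold. Protein-coding genes supplied 305 of the higher and 301 of the lower loci. The whole interval lay beyond 2-fold for 260 higher and 193 lower loci. A threshold of 4-fold left 106 higher and 60 lower loci, and a mean of at least 10 CPM left 181 and 141. Across the 14230 loci with reads in both libraries, Pearson's r of log2 CPM was 0.966; it is a correlation across loci, which are not independent replicates.

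**Figure D2:**
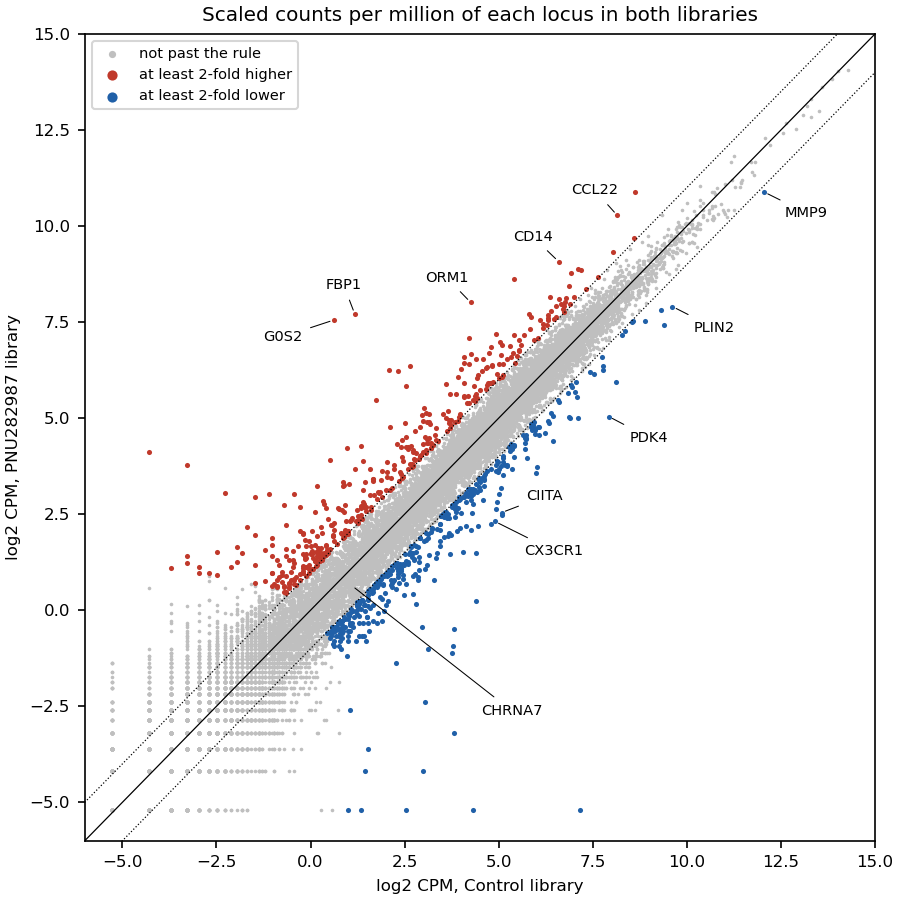
Log2 CPM of each locus in the Control library (horizontal axis) and the PNU282987 library (vertical axis), for loci with reads in both; the solid line marks equality and the dotted lines 2-fold. Loci at least 2-fold higher under the rule are red and those at least 2-fold lower blue; CD14 lies at 96.3 and 539 CPM and PDK4 at 242 and 32.9 CPM.

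Genes of sterol and fatty acid synthesis stood higher in the PNU282987 library as groups. In the cholesterol biosynthesis list, 22 of 24 measured members had a ratio above 1, and the median log2 ratio of 0.61 lay above all 10000 random lists matched on expression. Of these members 5 were at least 2-fold higher, among them STARD4, a sterol carrier, at 21.5 and 66.4 CPM, INSIG1, a sterol sensor, at 107 and 260 CPM, and HMGCS1 at 78.6 and 188 CPM. TM7SF2, a sterol reductase at 2.16 and 0.795 CPM, was the only member at least 2-fold lower; it was named after its values were seen. The fatty acid synthesis and desaturation list had a median of 0.64, above all random lists, with 13 of 14 members above a ratio of 1; its median was 0.47 with the trend over GC content and length removed and 0.36 over the 7 members that overlap no other locus, both above the middle 95%. PNPLA3, a lipid droplet acyl hydrolase, was 3.68-fold higher and ELOVL6, a fatty acid elongase, 2.67-fold higher.

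Genes of cholesterol efflux and lipid storage stood lower. The 12 LXR targets had a median log2 ratio of -0.54, below all random lists, and -0.34 with the trend over GC content and length removed, and 9 had a ratio under 1. The sterol exporter ABCG1 was 2.78-fold lower, at 81.4 and 29.2 CPM. The lipid storage and PPAR list had a median of -0.28 at percentile 0.38 of the random lists, with 14 of 18 members under a ratio of 1, and a median of -0.72 over the 15 members with at least 10 CPM and also over the 11 that overlap no other locus. Its members past the rule went both ways: PDK4, FABP4 and PLIN2 were lower and G0S2 was higher. FABP4, a fatty acid carrier, was 4.49-fold lower, at 276 and 61.4 CPM, and PLIN2, the coat protein of lipid droplets, 3.28-fold lower, at 784 and 239 CPM.

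MHC class II antigen presentation had the lowest median of all ranked lists. Of its 12 measured members 9 were at least 2-fold lower in the PNU282987 library, none was 2-fold higher, and the median log2 ratio of -1.10 lay below all random lists. Besides CIITA these included HLA-DMB at 117 and 32.3 CPM, HLA-DMA at 22.4 and 9.22 CPM and HLA-DPB1 at 7.39 and 2.63 CPM. Reads of the HLA genes can be shared between near-identical members, so single values are uncertain. In the interferon-stimulated list 21 of 23 members had a ratio under 1 and none passed the 2-fold rule; the median of -0.44 lay below all random lists. OAS3 had 229 and 173 CPM.

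In the macrophage identity list, 3 of 23 members were at least 2-fold higher and none lower: the lipopolysaccharide co-receptor CD14 (chromosome 5, 140631732 to 140633701) was 5.60-fold higher, at 96.3 and 539 CPM, the complement receptor chain ITGAM 3.44-fold higher and the complement receptor VSIG4 2.94-fold higher. The list's median of -0.07 lay within the middle 95% of the random lists, and over the 12 members that overlap no other locus it was -0.33, below that range. The microglia-associated list had a median of -0.32 at percentile 0.1, with 13 of 19 members under a ratio of 1, and a median of -0.18 at percentile 2.32 with the trend over GC content and length removed. CX3CR1 was its only member past the rule, while CSF1R had 1291 and 1059 CPM and the complement gene C1QC 1121 and 768 CPM. The disease-associated microglia list had a median of -0.38 at percentile 0.015 with no member past the rule; SPP1 had 16514 and 16700 CPM. With the trend over GC content and length removed, that median was -0.17 at percentile 3.47, within the middle 95%.

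Members of the phagocytosis and amyloid β uptake list had a median of -0.06 within the middle 95%, with CD14 and ITGAM the only members at least 2-fold higher among 29 and none lower. Over the 15 members that overlap no other locus the median was -0.28, below that range. Among 12 amyloid β degrading enzymes, with a median of -0.05 within the middle 95%, the protease PLAU was 2.76-fold higher and MMP9 2.24-fold lower, at 4232 and 1888 CPM. The lysosome and autophagy list had a median of -0.13, within the middle 95%, with none of its 35 members past the rule. Cathepsin D, CTSD, had 7562 and 5895 CPM, a log2 ratio of -0.36, or -0.05 with the trend over GC content and length removed.

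Inflammatory genes were divided. The NF-kB and inflammatory cytokine list had a median of 0.21 at percentile 99.2, with 18 of 27 members above a ratio of 1. The chemokine CCL20 was 2.66-fold higher on 45 and 112 reads, while CD40, a co-stimulatory receptor, and BIRC3, an apoptosis inhibitor, were 2.25-fold and 2.23-fold lower. Over the 18 members with at least 10 CPM the median was 0.19 at percentile 96.8, within the middle 95%. The JAK-STAT3 target list had a median of 0.42, above the middle 95%, with CEBPB 3.34-fold, BCL2 3.10-fold and MYC 2.27-fold higher. Over its 7 members that overlap no other locus the median was 0.06 at percentile 65.8, within the middle 95%. In the anti-inflammatory and alternative activation list, with a median of 0.06 within the middle 95%, the chemokine CCL22 was 4.38-fold higher, at 283 and 1241 CPM. ARG1 was 2.74-fold higher by its own reads, and its log2 ratio of 1.45 became 0.41 with the reads of an overlapping locus added. The immediate early and CREB target list had a median of -0.07 within the middle 95%, with EGR1 2.33-fold and EGR2 2.25-fold higher and IER2 3.69-fold lower.

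Of the stress, growth and housekeeping lists, 2 lay below the middle 95% of the random lists. The NRF2 target list had a median of -0.23 at percentile 0.6, with the transporter ABCC3 2.11-fold lower and the transporter ABCC2 higher on 32 and 63 reads, a log2 ratio of 1.07. With the trend over GC content and length removed, ABCC2 had a log2 ratio of 0.97, within 2-fold. Over the 14 members of the list that overlap no other locus the median was -0.19 at percentile 6.08, within the middle 95%. The proliferation list had a median of -0.21 at percentile 0.13 with 22 of 30 members under a ratio of 1 and none past the rule; MKI67 had 130 and 148 CPM. Medians within the middle 95% were 0.01 for the integrated stress response, -0.05 for the unfolded protein response, 0.16 for the heat shock response, -0.03 for hypoxia and glycolysis, -0.05 for p53 targets and -0.01 for apoptosis and inflammasome effectors. In these lists HK2 was 2.15-fold, PFKFB4 2.79-fold, PLK3 3.14-fold and PMAIP1 2.34-fold higher, and GSDMD 2.17-fold lower. The log2 ratio of GSDMD was -1.12, or -0.90 with that trend removed, within 2-fold. ASNS was lower by its own reads, at 14.1 and 6.72 CPM, but its log2 ratio of -1.07 became 0.072 with the reads of 3 overlapping loci added. Core histones had a median of -0.39, nuclear-encoded oxidative phosphorylation 0.00, mitochondrially encoded genes -0.05, cytosolic ribosomal proteins -0.11 and reference genes -0.13, all within the middle 95%. ACTB had 11564 and 8205 CPM, a log2 ratio of -0.50, and GAPDH 1920 and 1524 CPM, a log2 ratio of -0.33. Both were lower under every scaling tried. With the trend over GC content and length removed, the log2 ratio was -0.30 for ACTB and -0.096 for GAPDH. Of the metallothionein list 3 members were measured, MT2A among them with 6.70 and 8.42 CPM.

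Of the marker lists of other cell types, 2 lay below the middle 95% of the random lists. Granulocyte and monocyte progenitor markers had a median of -0.62, below all random lists, or -0.41 with the trend over GC content and length removed, with 12 of 14 under a ratio of 1, S100A12 2.13-fold lower and CD177 2.18-fold lower. With that trend removed, the log2 ratio of CD177 went from -1.12 to -0.93, within 2-fold. Mast cell, basophil and eosinophil markers had a median of -0.49 at percentile 0.78 with none of the 8 past the rule; PRG2 had 45.0 and 31.7 CPM. Medians within the middle 95% were 0.35 for pluripotent stem cell, -0.20 for endothelial, 0.15 for mesenchymal, -0.16 for megakaryocyte, 0.15 for hepatocyte and -0.27 for neural markers. GP1BA, a platelet receptor chain, was 3.92-fold lower on 151 and 36 reads, and the collagen gene COL3A1 had 1163 and 1349 CPM. The endothelial median was -0.44 over the 4 members with at least 10 CPM. It was -0.47 over the 10 members with at least 10 reads in both libraries together and no CPM filter. Both values lay below the middle 95%. The mesenchymal median was 0.29 over the 9 members that overlap no other locus, above the middle 95%. Among lymphoid markers IL7R was 2.17-fold lower, at 134 and 61.6 CPM, and NKG7 had 30.5 and 19.7 CPM. EPOR was the only erythroid marker measured, at 3.90 and 3.24 CPM.

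**Figure D3:**
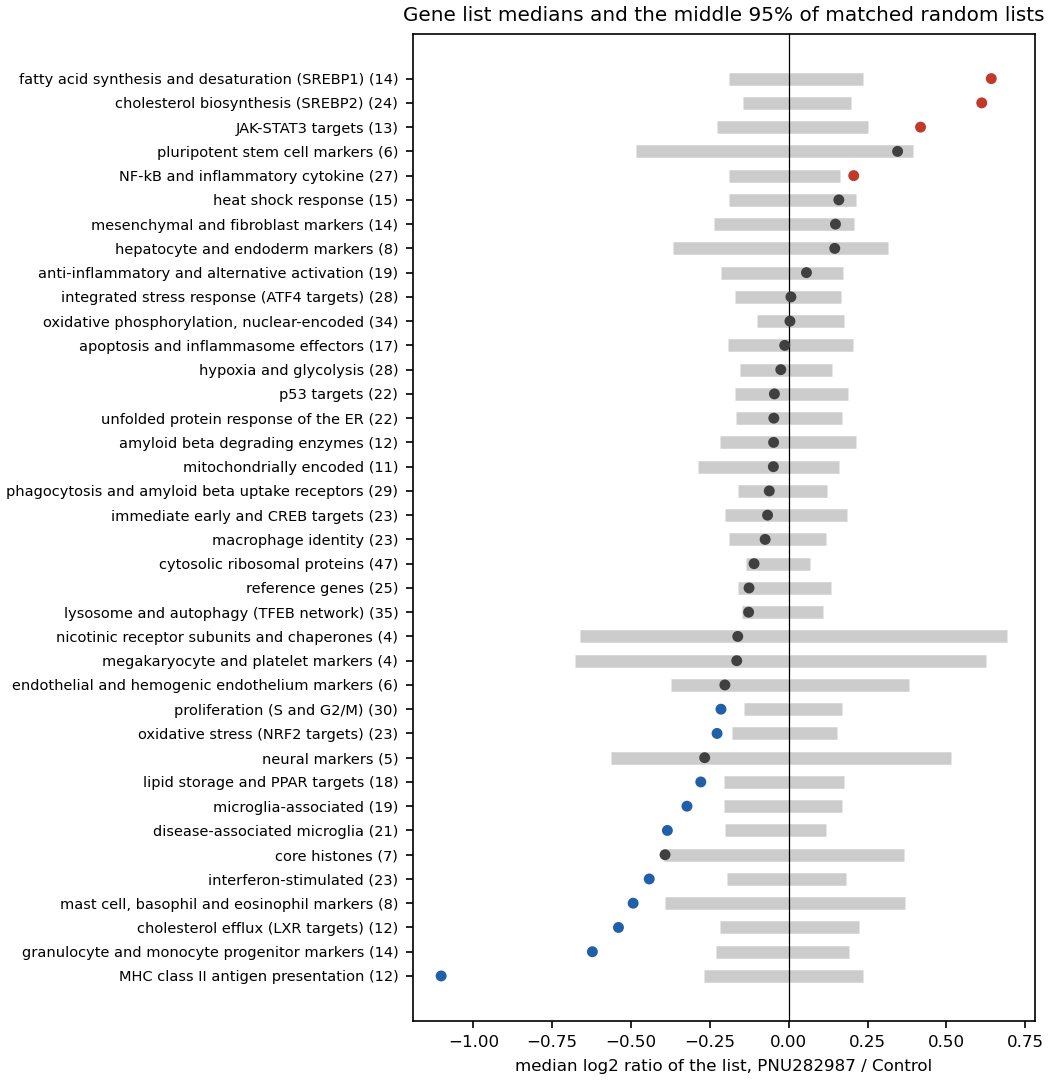
Median log2 ratio, PNU282987 over Control, of the 38 gene lists with at least 4 measured members (number in brackets), with the middle 95% of 10000 matched random lists as grey bars. Red and blue medians lie above and below that range; MHC class II lies at -1.10 and fatty acid synthesis at 0.64.

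Of the 38 ranked lists 4 lay above and 10 below the middle 95% of the random lists. By chance 1.9 would be expected if the members of a list varied independently, as in the random lists. Members regulated together can move together between cultures, so the excess over 1.9 cannot be read as evidence of an effect. Many lists share members, and the percentiles describe these 2 libraries, not the treatment.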

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

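With 1 library per group, leaving out a library is not possible, and TPM or FPKM alternatives were not run because the table used here has only counts. No paired analysis was possible because the comparison comes from no test and each group has 1 library. The counts of 423 higher and 401 lower loci stayed within 1.5 times under library totals, DESeq2 and upper-quartile factors, a stricter interval, thinning, annotated or protein-coding loci only, removal of the genes with the most reads, and, chosen after seeing the data, halved counts and removal of the GC content and length trend. They moved by construction to 950 and 879 without the CPM filter, 181 and 141 at a mean of at least 10 CPM, 1251 and 1235 at 1.5-fold, 106 and 60 at 4-fold, and 260 and 193 with the whole interval beyond 2-fold. Among loci that overlap no other annotated locus, a subset of 6869 chosen after seeing the data, they were 184 and 192. GC content and length were known for 333 of the 423 higher and 329 of the 401 lower loci, and of these 266 and 252 were called with the trend removed. Of the 108 named genes with both known, 57 then lay outside their counting interval, and the log2 ratios of CD177 (-0.93), GSDMD (-0.90), MMP9 (-0.90) and ABCC2 (0.97) came within 2-fold, which ended their calls. Across loci the log2 ratio had a Spearman correlation of -0.37 with GC content and 0.32 with transcript length, over loci that are not independent replicates; the cause was not tested. The 14 lists outside the middle 95% kept that side under each of the 3 other scalings, and 13 of them with the trend removed. Lists that left the middle 95% only under an alternative, besides those in the report, were the anti-inflammatory list with the trend removed (0.20), heat shock with the trend removed (0.19) and with random lists also matched on length (0.16), and core histones against protein-coding random lists (-0.39). The log2 ratio of CHRNA7 was -0.42 with library totals, -0.45 with DESeq2 factors and -0.66 with the trend removed; the interval then excludes equality, but leaves out the error of the trend. With the reads of overlapping loci added, ASNS went to 0.072 and MIR6502 to 0.12, opposite in sign to their own reads. Low expression, and so few reads per gene, limits CHRNA7 and the other nicotinic subunits.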

Other observations

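Further protein-coding genes, chosen here after their values were seen, had some of the greatest differences outside the gene lists. SEMA6B, a semaphorin, was 9.25-fold higher in the PNU282987 library, at 42.5 and 393 CPM, and CLMN 7.33-fold higher. THBD, the thrombin receptor thrombomodulin, was 5.69-fold higher, TREM1, an amplifier of myeloid inflammation, 5.13-fold higher and the cytokine OSM 5.59-fold higher. In the other direction LAMP3 had 27.7 and 4.75 CPM, the chemokine receptor CCR7 19.6 and 5.79 CPM, and the antigen-presenting molecule CD1E 506 and 100 reads.

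Of the tests below, those on hepatocyte transcripts, on overlaps of the 12 vitamin D targets and on the genes G0S2 and NR1I2 were chosen after the result was seen. Many of the genes with the greatest excess in the PNU282987 library are known targets of the vitamin D receptor, CYP24A1, CD14, THBD and FBP1 among them. Reads moved between annotated loci are argued against as the cause for the set, since only 3 of 12 such genes overlap another annotated locus; of these, with the overlapping reads added, G0S2 gained none, the log2 ratio of CD14 went from 2.48 to 2.28 and that of ASAP2 from 4.17 to 1.48. Hepatocyte-like cells are argued against as the source of ORM1, since ALB, APOA1, APOA2 and TTR were together 2.67 CPM higher while ORM1 was 239 CPM higher; SERPINA1, also a macrophage gene, was 23.9 CPM lower. A candidate explanation is vitamin D receptor signalling in this library: 13 further targets not looked at before had 11 measured members, 7 of them at least 2-fold higher, such as CAMP at 16.9 and 46.4 CPM, and their median log2 ratio of 1.30 lay at percentile 100 of matched random lists, as it did with the GC content and length trend removed; without THEMIS2, which is also among the 40 highest-ranked protein-coding genes, 6 of 10 were at least 2-fold higher and the median of 1.28 lay at the same percentile. What would have activated the receptor was not tested, and the agonist, the amyloid β named in the treatment field and a difference between cultures all stay open with 1 library per group.

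At 29 loci the libraries lay at least 64-fold apart, 17 of them, or 58.6%, assembled loci with 0 reads in a library; assembled loci make up 2.31% of all loci compared. Among the 12 annotated loci 83.3% overlapped another annotated locus, above the 75% that 95% of matched random sets stayed at or under. In both, overlaps with loci that held no reads were counted too, such as those of G0S2 and NR1I2. This share therefore cannot decide whether reads were assigned between overlapping loci, which may contribute. Adding the overlapping reads does not settle this for a locus within a host gene that holds most of the reads, such as SNORA7A with 227 of 10064 Control reads, where a true loss would look alike. Assignment between annotated loci does not account for G0S2 and NR1I2, since the annotated loci that overlap them held 0 Control reads, and CYP24A1 and FBP1 overlap no annotated locus. The assembled loci have no position in the table used here, so assignment of reads between them and these genes was not tested and stays open.

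The MHC class II list was lower by a median log2 ratio of -1.10, and a trend with GC content or transcript length is argued against, since the median was -1.17 with it removed. A lower share of dendritic-like cells may contribute. The 14 dendritic cell markers not looked at before had 10 measured members, 8 under and 2 above a ratio of 1, with a median of -0.62, at percentile 0.11 of matched random lists, between the -0.75 that this explanation was set to need and the -0.5 that would have spoken against it. LAMP3, CCR7 and CD1E, lower and already seen, were not among these markers, so the median leaves them out. CD1C had 21.6 and 8.45 CPM, CD1B 136 and 35 reads, ZBTB46 36.3 and 21.6 CPM and FLT3 57 and 28 reads. The abundant CD83 had 220 and 193 CPM, CD1A 115 reads in each library and SIGLEC6 45 and 105 reads. FSCN1, with 426 and 225 CPM, is also found in other cells. With the trend over GC content and length removed, the median of the markers was -0.54, also between both bounds. Each group has 1 library made from all its cells together. Wherever that median lies, a lower share of such cells and lower transcription of MHC class II genes within each cell cannot be told apart.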
